A study of Mus musculus with 9 samples.

How the data were processed

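Gene expression was measured on 9 Affymetrix whole-transcript mouse arrays, 3 for each of 3 populations of phagocytes sorted from Peyer's patches, the lymphoid follicles of the small intestine. Per the labels' protocols, patches were digested enzymatically, dead cells were removed, cells carrying CD11c were enriched on magnetic beads, and populations were sorted by flow cytometry with antibodies to CD11c, SIRP, BST2, C5aR, CD4 and MHC class II. The gates themselves are not given in the sources used here. Total RNA from the sorted cells was amplified with a low-input kit, and the sense cDNA was fragmented and labelled with biotin.

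The deposited values are log2 expression values, 1 per transcript cluster (the probe set of a gene on this array) and array. Per the submitters' processing notes, they were made with RMA and Affymetrix Power Tools; versions and settings are not given in the sources used here. All 33793 transcript clusters were tested, with values from 0.719 to 13.2, and no further normalization or filter was applied. The platform annotation gave exactly 1 gene symbol to 23521 clusters, several to 1814 and none to 8458. Only clusters with 1 symbol are named, and for the 1082 genes with several clusters the one with the highest mean over all 9 arrays stands for the gene, which left 22180 genes.

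Samples were grouped by their titles, which also give the replicate numbers. The source fields of C5aR- LysoDC arrays 2 and 3 name other receptors, while their titles and descriptions name C5aR, and the titles were followed. Arrays of C5aR+ LysoDC and LysoMac with the same number deviated together from their group means (r = 0.16, 0.26 and 0.41 over clusters), which the labels do not explain, so values with the replicate number as a block stand beside results of that comparison whose call it changed. In the other comparisons not every such correlation was over 0.1, and this choice by comparison was made after the blocked calls had been seen. Nothing in the labels says whether the 3 arrays of a population came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: the median SE of a difference between populations was 0.20 on the log2 scale.

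Differences were tested with limma 3.58.1 in R 4.3.3, with 1 mean per population over all 9 arrays (6 residual degrees of freedom), moderated variances and two-sided tests. Adjusted p-values are Benjamini-Hochberg values over all 33793 clusters, and 0.05 was the threshold. A moderated F test covered the 3 populations together. For 29 gene lists, limma's camera compared each list with all other genes, with a preset correlation of 0.01, and the 87 tests were adjusted together. A second run estimated the correlation from the data. The lists held 611 genes, of which 553 were matched, and 18 of the rest lie only on clusters with several symbols. The distance between populations was the sum over clusters of squared differences of means, less the part that the spread within populations contributes, with a jackknife SE over arrays.

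The lists, the tests of the comparisons, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the targets of the sort antibodies and the lysozyme genes, the 10 largest increases and the 10 largest decreases among genes that passed the test with no overlap between the 3 arrays of either population, and up to 4 members of each list with the smallest adjusted p. Where no member of a list passed, the rule takes its 2 most highly expressed members. Predicted genes, small RNA genes, olfactory receptors and antigen receptor segments were left out of the largest changes. The alternatives were a replicate block, median centring, quantile normalization and cyclic loess between arrays, a filter on dim probes, probes with 1 symbol only, an intensity trend or robust variances in limma, array weights, fits of the 2 compared populations alone, a 2-fold minimum, the mean of all probes of a gene, the rotation test fry and leaving out each array. One weight per population was added after seeing the data.

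The fit was checked on 10 simulated data sets with the means and variances of the real clusters, in which 200 of 33793 clusters differed between C5aR+ and C5aR- LysoDC. It recovered 38.1% of clusters changed 2-fold and 93.4% of those changed 4-fold, and 4.00% of the calls were false. The simulated distance of 929 was estimated as 927 on average, and camera called 10 of 10 shifted lists and 0 of 200 unshifted ones. These simulations had no correlation between genes.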

Results

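Expression was profiled in 3 populations of lysozyme-expressing phagocytes from mouse Peyer's patches: macrophages (LysoMac) and dendritic cells (LysoDC) with or without C5aR, the receptor for the complement fragment C5a. Each population was represented by 3 arrays. The series asks whether the C5aR+ LysoDC form a population of their own. Array medians lay between 3.39 and 3.65 on the log2 scale. Arrays of the same population correlated at a mean r of 0.974 to 0.978 in C5aR+ LysoDC and 0.977 to 0.980 in C5aR- LysoDC, but at 0.948 to 0.965 in LysoMac. Not every array lay closest to its own population. LysoMac array 3 had a mean r of 0.954 to its own population and 0.968 to the others, while every other array had the higher mean r within its own. C5aR+ LysoDC array 3 correlated at 0.982 with C5aR- LysoDC array 3, against 0.974 with each C5aR+ LysoDC array. LysoMac array 2 had the narrowest interquartile range of the 9 arrays (2.16) and the lowest mean r to the other populations (0.933). The mean variance within LysoMac was 0.179, against 0.0958 in C5aR+ LysoDC and 0.0854 in C5aR- LysoDC. The fit uses 1 variance per cluster for all populations, so p-values against LysoMac tend to be too small. Those between the LysoDC populations tend to be too large. With 1 weight per population, chosen after the data were seen, calls of C5aR- LysoDC against LysoMac went from 518 to 254. Calls of C5aR+ LysoDC against LysoMac went from 17 to 12, and those between the LysoDC populations from 34 to 112. Over the 3 populations, 255 transcript clusters differed (limma's moderated F test). That count became 71 and 153 without LysoMac arrays 1 and 2, 96 without C5aR+ LysoDC array 2, and 108, 50 and 162 without C5aR- LysoDC arrays 1, 2 and 3.

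The genes of the sort antibodies and of lysozyme separated the populations in part. C5ar1 averaged 4.68 in C5aR+ LysoDC, 0.08 ± 0.29 from its level in LysoMac, and 3.01 in C5aR- LysoDC. It fell by 1.59 ± 0.29 (SE, n = 3 per population) from LysoMac to C5aR- LysoDC (adjusted p = 0.0379), a call lost when each array was centred on its median. The 1.67 ± 0.29 between the LysoDC populations, with no overlap between arrays, did not pass over all genes (adjusted p = 0.105), although C5ar1 was the 1 of 10 sort genes that passed adjusted over the list alone. Its mean of 3.01 lay below the median of every array, so 1.59 and 1.67 are lower bounds. Cd4 averaged 7.13 in LysoMac, 4.74 in C5aR+ LysoDC and 4.44 in C5aR- LysoDC, and fell by 2.69 ± 0.36 from LysoMac to C5aR- LysoDC (adjusted p = 0.00964). The lysozyme genes Lyz2 and Lyz1 were high in every population (Lyz2 between 10.6 and 11.3), and neither they nor Itgax, Sirpa and Bst2 passed in any comparison.

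**Figure D1:**
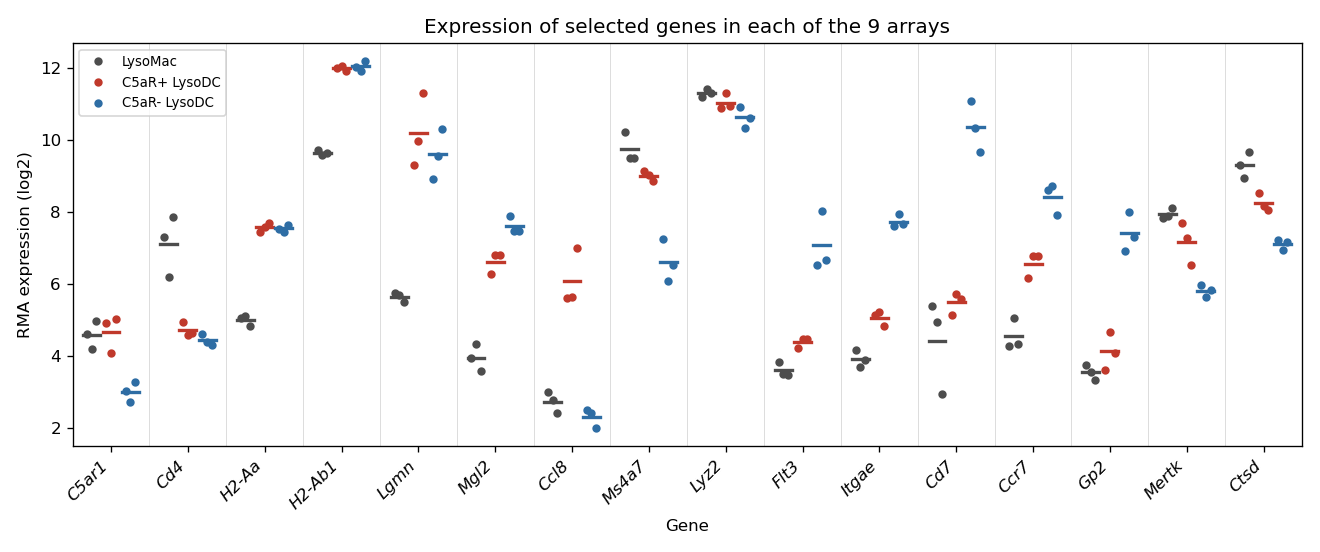
RMA expression on the log2 scale (vertical axis) of 16 genes (horizontal axis) in each of the 9 arrays; points are arrays, colours are populations and bars are means of 3 arrays. H2-Aa and H2-Ab1 lie higher in both LysoDC populations than in LysoMac, Ccl8 is highest in C5aR+ LysoDC (mean 6.09), and Itgae, Cd7 and Gp2 are highest in C5aR- LysoDC.

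C5aR+ LysoDC were set against C5aR- LysoDC to ask what distinguishes the cells that carry the receptor. The chemokine gene Ccl8 was 3.78 ± 0.36 higher on the log2 scale in C5aR+ cells (adjusted p = 0.0124), and Ms4a7, a membrane protein gene of macrophages, was 2.39 ± 0.30 higher (adjusted p = 0.0346). The mean of Ccl8 in C5aR- cells, 2.31, lay below the median of every array, so 3.78 is a difference of signals that stands only as a lower bound for RNA, and no fold is given. In the other direction, 32 clusters were lower in C5aR+ cells, among them Itgae (CD103) by -2.67 ± 0.18 (adjusted p = 0.00364). With the replicate number as a block, 12 clusters were higher and 47 lower. Flt3, the cytokine receptor that sustains dendritic cells, was lower by -2.69 ± 0.34 (adjusted p = 0.0355) and Cd7 by -4.88 ± 0.59 (adjusted p = 0.0335). Gp2, Srgap3, Tmprss11d, Tnip3, Plekhs1, Car2, S100a4 and Plp2 were also lower, with differences of -2.67 to -3.48. Among them Srgap3, Tmprss11d and Plekhs1 averaged 2.64, 2.25 and 2.61 in C5aR+ cells, again below every array median, so their differences are lower bounds too. The genes H2-Aa, H2-Ab1 and H2-Eb1 of MHC class II did not pass, with differences of 0.03, -0.05 and -0.02. Over all 23 genes of MHC class II presentation and co-stimulation 16 differences were below 0, with a median of -0.05 (adjusted p = 0.00932, but adjusted p = 0.347 with an estimated correlation), and 3 fell adjusted over the list alone and 0 over all genes in limma.

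The list of conventional dendritic cell genes was lower in C5aR+ than in C5aR- LysoDC, with a median of -0.91 over 28 measured members (camera, adjusted p = 1.89e-19; adjusted p = 0.0115 with an estimated correlation). Of these, Flt3, Itgae and Bcl11a fell and 25 did not pass, while 14 fell adjusted over the list alone. The macrophage list was higher in C5aR+ cells, with 26 of 28 differences above 0 and a median of 0.60 (adjusted p = 2.00e-11; adjusted p = 0.0340 with an estimated correlation). Of its genes 0 passed over all genes in limma, 12 had an unadjusted p under 0.05 and 8 passed adjusted over the list alone. Csf1r, the receptor of a macrophage growth factor, differed by 0.87 ± 0.29 (adjusted p = 0.581). Of 31 cell cycle genes 30 had differences below 0, with a median of -0.83 (adjusted p = 1.63e-22, but adjusted p = 0.119 with an estimated correlation), and 14 fell adjusted over the list alone, 17 at an unadjusted p under 0.05 and 0 over all genes in limma. The medians of lysosomal genes (0.45, adjusted p = 0.383 with an estimated correlation) and of chemokines (0.48, adjusted p = 0.264 with an estimated correlation) were calls only at the preset correlation. Among markers of other cells, Gp2, Pglyrp1 and Cdh1 of the epithelial and M cell list fell, by -3.28, -2.54 and -2.11, while the median of its 26 genes was -0.020 (adjusted p = 0.0133, but adjusted p = 0.383 with an estimated correlation).

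In this comparison 3463 clusters (10.2%) showed no overlap between the 3 and 3 arrays, where chance gives 10%. The 34 calls became 1, 7 and 8 without C5aR+ LysoDC arrays 1, 2 and 3, 6, 5 and 67 without C5aR- LysoDC arrays 1, 2 and 3, and 9, 17 and 25 without LysoMac arrays 1, 2 and 3. Of 16 named genes that passed, only Itgae passed in all 14 other settings tried on named genes. These 14 were the replicate block, median centring, quantile normalization, cyclic loess, the mean of all probes of a gene and leaving out each array. Named genes were not followed in the fit of the 2 populations alone, with weights or in the remaining alternatives. The second, dimmer probes of Bcl11a (-0.08) and Cdh1 (0.08) did not pass, and S100a4 lost its call after quantile normalization or cyclic loess.

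C5aR+ LysoDC were also set against LysoMac, to ask what distinguishes them from macrophages of the same tissue. MHC class II genes were higher in C5aR+ LysoDC: H2-Aa rose by 2.57 ± 0.14 (adjusted p = 0.000191), H2-Ab1 by 2.34 ± 0.13 (adjusted p = 0.000191), H2-Eb1 by 2.48 ± 0.18 (adjusted p = 0.00196) and H2-DMb1, which helps load peptides, by 1.66 ± 0.17 from a mean of 2.50, below every array median (adjusted p = 0.0132). The largest named increase was that of Lgmn, a lysosomal protease, by 4.54 ± 0.49 or 23.2-fold (adjusted p = 0.0150). Ccl8 rose by 3.35 ± 0.36 (adjusted p = 0.0150, but 0.0507 with the replicate number as a block), from a mean of 2.74 that also lay below every array median and makes the rise a lower bound. The increases further included Mgl2, a lectin of dendritic cells and macrophages, by 2.66 ± 0.23 (adjusted p = 0.00672), and Plbd1, Pld4 and H2-Ea by 2.97, 2.84 and 2.72. No cluster was lower in C5aR+ LysoDC in limma's test, where 897 were lower and 1195 higher at an unadjusted p under 0.05, so that all 17 calls were increases. Pf4 differed by 3.25 ± 0.42 (adjusted p = 0.0502) and Cd4 differed by -2.39 ± 0.36 (adjusted p = 0.104).

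The MHC class II list rose, with a median of 0.84 over 23 members (adjusted p = 1.03e-18; adjusted p = 0.0115 with an estimated correlation). Over all genes 5 members rose, and 12 did adjusted over the list alone. Conventional dendritic cell genes were higher with a median of 0.49 (adjusted p = 3.10e-08; adjusted p = 0.0353 with an estimated correlation), 1 of 28 passing over all genes and 7 adjusted over the list alone. B cell markers, which B cells express together with MHC class II, moved the same way: their median was 0.75 over 16 genes (adjusted p = 3.60e-12; adjusted p = 0.0348 with an estimated correlation), with 9 passing adjusted over the list alone, 9 at an unadjusted p under 0.05 and 0 over all genes in limma. Monocyte genes (median 0.36, adjusted p = 5.41e-05, but adjusted p = 0.119 with an estimated correlation), plasma cell markers (0.24, adjusted p = 0.00391) and stromal markers (0.09, adjusted p = 0.00633) were calls only at the preset correlation, the latter 2 lists each having an adjusted p = 0.383 with an estimated correlation. Monocyte and plasma cell genes lay highest in C5aR+ LysoDC array 3, 0.90 and 0.61 above the mean of all arrays, against 0.032 or less in arrays 1 and 2. Among the brightest genes of the B cell list, Cd79b differed by -0.18 ± 0.35 and Ighm by 0.44 ± 0.35, where 6 other clusters of Ighm differed by -0.52 to 1.60 and 0 of them passed. Chemokines had a median of 0.54 (adjusted p = 0.119 with an estimated correlation), of which 1, Ccl8, passed over all genes and 10 adjusted over the list alone. Macrophage genes had a median of 0.08 (adjusted p = 0.0982, 0.0189 with the replicate number as a block; adjusted p = 0.458 with an estimated correlation).

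Quantile normalization gave 19 increases and 3 decreases in place of 17 and 0, and cyclic loess 17 and 3. In this comparison 2666 clusters (7.89%) showed no overlap between arrays, where chance gives 10%. The 17 increases became 4 and 11 without LysoMac arrays 1 and 2, 4 and 9 without C5aR+ LysoDC arrays 2 and 3 and 11 without C5aR- LysoDC array 2, with 4 and 3 decreases without LysoMac arrays 2 and 3 and 1 without C5aR- LysoDC array 2. Of 10 named genes only H2-Aa, H2-Ab1 and H2-Eb1 passed in all of the same 14 settings, which leave out the fit of the 2 populations alone and the weights.

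C5aR- LysoDC differed most from LysoMac, with 381 clusters higher and 137 lower (490 and 219 with the replicate number as a block). Among the conventional dendritic cell genes, Itgae rose by 3.82 ± 0.18 (adjusted p = 7.53e-05), the migration receptor gene Ccr7 by 3.86 ± 0.29 (adjusted p = 0.000966), Mgl2 by 3.66 ± 0.23 (adjusted p = 0.000350) and P2ry10 by 3.39 ± 0.29 (adjusted p = 0.00143). Cd7 rose by 5.94 ± 0.59, or 61.3-fold, Plac8 by 4.72 ± 0.55 and S100a10 by 4.43 ± 0.52, and Ifi205, Flrt3, Plp2, Lgmn, Plekhs1 and Gp2 rose by 3.86 to 4.49. In LysoMac Ifi205, Flrt3 and Plekhs1 averaged 3.09, 2.67 and 2.21, below every array median, so these rises are lower bounds. The decreases included Mertk, a receptor for dying cells that macrophages carry, by -2.13 ± 0.26 (adjusted p = 0.00742), Ctsd, a lysosomal protease, by -2.19 ± 0.21 (adjusted p = 0.00245), Ms4a7 by -3.13 ± 0.30 (adjusted p = 0.00265) and Gpnmb by -2.84 ± 0.51 (adjusted p = 0.0331). Tspan10, Mmp2, Plxna2, Dkk3, Pmp22, Il18bp, Clec4d and the complement gene C2 fell as well, with differences of -2.74 to -3.92.

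Of the conventional dendritic cell list 14 of 28 members rose and none fell, against 18 risen and 1 fallen adjusted over the list alone, with a median of 1.26 (adjusted p = 1.24e-18; adjusted p = 0.0115 with an estimated correlation). Of the MHC class II list 11 of 23 rose, 16 adjusted over the list alone, with a median of 1.66 (adjusted p = 1.10e-17; adjusted p = 0.0115 with an estimated correlation), H2-Ab1 by 2.39 ± 0.13. Cell cycle genes rose in 7 of 31 cases, and in 25 adjusted over the list alone, Kif23 by 1.71 ± 0.22 and Cdc6 by 1.51 ± 0.21, with a median of 1.20 (adjusted p = 1.63e-22, but adjusted p = 0.119 with an estimated correlation). Of the macrophage list Mertk, Cx3cr1, Vcam1 and Apoe fell and none rose, 6 having fallen and 2 risen adjusted over the list alone, and the median was -0.28 (adjusted p = 0.00932, but adjusted p = 0.347 with an estimated correlation). C1qb and C1qc, subunits of the first complement component, fell by -0.99 ± 0.18 and -1.12 ± 0.17, calls that were lost with each array centred on its median. Markers of other cells moved here too: Cr2, Blk and Pou2af1 of the B cell list rose by 1.64, 1.82 and 0.62, Jchain of the plasma cell list by 3.10, and Gp2, Pglyrp1, Epcam and Cdh1 of the epithelial and M cell list by 1.54 to 3.86. Lum and Kdr of the stromal list rose by 2.77 and 0.82, Mmp9 and Trem1 of the neutrophil list by 2.00 and 1.46, Il7r of the innate lymphoid list by 3.58 and Atp1b1 of the plasmacytoid dendritic cell list by 3.23. Cr2, Epcam, Lum and Atp1b1 averaged 3.10, 3.21, 2.18 and 3.17 in LysoMac, below every array median. Of these lists only that of B cells passed, with a median of 0.60 and 14 of 16 differences above 0 (adjusted p = 6.30e-06, but adjusted p = 0.119 with an estimated correlation). The epithelial and M cell list, with 4 of 26 genes risen, had a median of -0.024 (adjusted p = 0.0814).

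**Figure D2:**
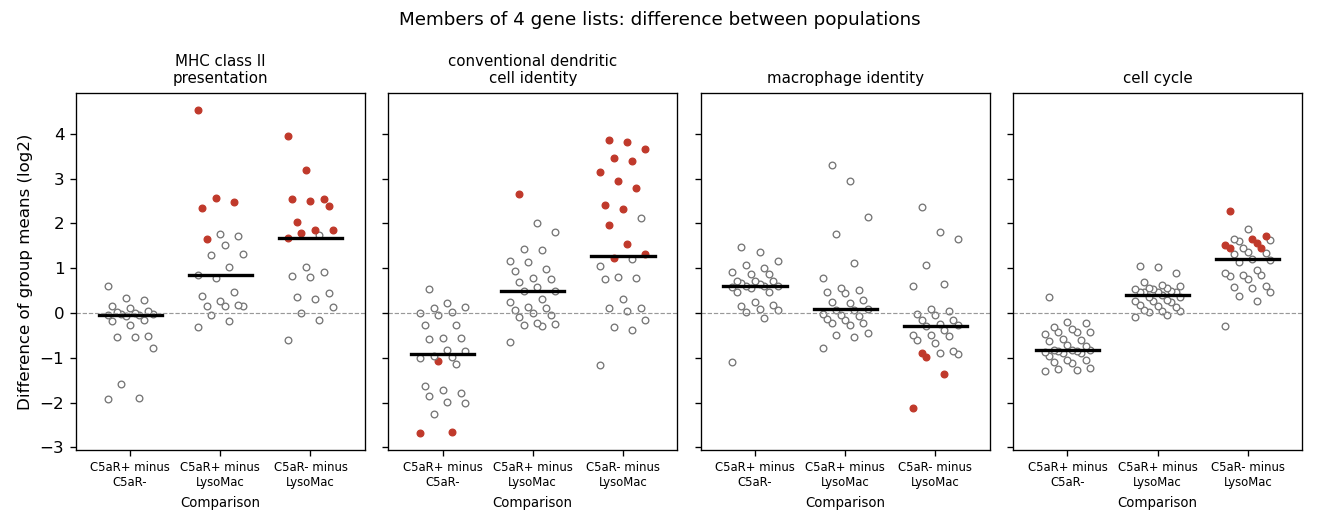
Differences of population means on the log2 scale (vertical axis) for each measured member of 4 gene lists in the 3 comparisons (horizontal axis); filled points passed at an adjusted p under 0.05 over all genes, open points did not, and black bars are list medians. The median of the conventional dendritic cell list was -0.91, 0.49 and 1.26 in the 3 comparisons, and that of the MHC class II list was -0.05, 0.84 and 1.66.

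Quantile normalization gave 436 increases and 274 decreases, and cyclic loess 444 and 291. In this comparison 4784 clusters (14.2%) showed no overlap between arrays, where chance gives 10%. The 518 calls became 161 and 1256 without LysoMac arrays 1 and 3, 363 (219 of them increases) without LysoMac array 2, 301 without C5aR+ LysoDC array 2, and 283, 130 and 320 without C5aR- LysoDC arrays 1, 2 and 3. In all, 31 of 70 named genes passed in all of the same 14 settings, which leave out the fit of the 2 populations alone and the weights.

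Genes shared by the comparisons were counted last. Ccl8 alone was higher in C5aR+ LysoDC than in both other populations (0 clusters were with the replicate number as a block), and 0 clusters were lower than in both in limma's test, against 92 and 44 at an unadjusted p under 0.05. Ccl8 kept both calls without C5aR+ LysoDC array 3 or C5aR- LysoDC array 3, and the count was 0 without each of the other 7 arrays. Against LysoMac, 16 clusters were higher in both LysoDC populations, among them Lgmn, H2-Aa, H2-Ab1, H2-Eb1, H2-DMb1 and Mgl2. Independent lists would share 0.192, and 100 simulations of unchanged groups, both set against the same simulated LysoMac arrays, shared 0. Simulations without effects yield almost no calls and independent lists leave out the shared arrays, so neither value says how many of the 16 those arrays bring. The 16 became 4 without LysoMac array 1, 4 and 8 without C5aR+ LysoDC arrays 2 and 3 and 10 without C5aR- LysoDC array 2. In both LysoDC populations 0 clusters were lower (465 at an unadjusted p under 0.05), with 4 and 3 without LysoMac arrays 2 and 3 and 1 without C5aR- LysoDC array 2. The differences of the LysoDC populations from LysoMac correlated across genes at 0.755 (simulated 0.50), with a covariance of 0.130 (simulated 0.0326), and genes are not independent replicates. The simulation gave all populations 1 variance per cluster, while LysoMac varied more (mean variance 0.179, against 0.0958 and 0.0854). Its values are therefore too low for the shared arrays, and the excess over them is too large. The 3 LysoMac arrays are too few to be split. Part of the excess comes from the shared arrays, and how much was not computed. Over all clusters, the squared distance was 1345 ± 1270 (jackknife SE) between the LysoDC populations, 1217 ± 2693 between C5aR+ LysoDC and LysoMac and 4885 ± 3179 between C5aR- LysoDC and LysoMac. C5aR+ LysoDC lay at 0.51 ± 0.35 of the way from C5aR- LysoDC to LysoMac, so these arrays did not resolve which of them they resemble more. The distance of C5aR+ LysoDC to LysoMac was -595, 555 and 3692 without LysoMac arrays 1, 2 and 3 and 391 without C5aR+ LysoDC array 3. The distance between the LysoDC populations was 768 and 2330 without C5aR+ LysoDC arrays 1 and 3 and 562 without C5aR- LysoDC array 2. That of C5aR- LysoDC to LysoMac was 2896 and 7727 without LysoMac arrays 1 and 3, and the position 0.83 without LysoMac array 1.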

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

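One weight per population was chosen after the data were seen. No call of a transcript cluster changed sign in any setting that was compared cluster by cluster. Median centring, an intensity trend, robust variances and a 2-fold minimum kept every count within 1.5 times the reported one. The counts of clusters higher and lower in C5aR+ than in C5aR- LysoDC were 2 and 32. Other settings gave 7 higher after quantile normalization, 8 and 54 after cyclic loess, 6 and 49 without dim probes, 5 and 52 over probes with 1 symbol (both with fewer tests). They gave 1 and 6 in a fit of the 2 populations alone (fewer arrays), 23 and 101 with array weights and 19 and 93 with one weight per population. For C5aR+ LysoDC against LysoMac (17 and 0), array weights gave 653 and 713, the fit of the 2 populations alone 4 higher, and quantile normalization and cyclic loess each 3 lower. For C5aR- LysoDC against LysoMac (381 and 137), array weights gave 2991 and 3691 and one weight per population 193 and 61. There the fit of the 2 populations alone gave 189 and 48, quantile normalization 274 lower and cyclic loess 291 lower. Array weights rested on LysoMac array 1, with a weight of 7.13 against 0.24 and 0.35 for LysoMac arrays 2 and 3. Higher in C5aR+ LysoDC than in both others were 0 with one weight per population or the fit of the 2 populations alone, and 2 with array weights, which also gave 2 lower. Higher in both LysoDC populations than in LysoMac were 569 with array weights and 3 in the fit of the 2 populations alone. Lower in both were 614 with array weights and 3 after quantile normalization or cyclic loess. The F test gave 5369 with array weights. The 33 gene list calls became 7 with an estimated correlation and 17 with fry, which tests each list on its own. Except where noted, the cause was not tested. Leaving out 1 array at a time gave 0 to 3 higher and 1 to 65 lower for C5aR+ against C5aR- LysoDC, 4 to 17 and 0 to 4 for C5aR+ LysoDC against LysoMac, 108 to 822 and 22 to 434 for C5aR- LysoDC against LysoMac. It gave 0 to 1 and 0 to 0 apart from both others, 4 to 15 and 0 to 4 in both LysoDC populations, 50 to 335 in the F test, and 27 to 41 list calls. The squared distances ran from 562 to 2330, -595 to 3692 and 2896 to 7727, and the position from 0.35 to 0.83, while scaling moved none by more than its SE. In the comparisons with C5aR- LysoDC not every same-numbered pair deviated together: the lowest correlations of deviations were -0.027 and -0.11, the others 0.13 to 0.23. Of all 9 same-numbered pairs 7 lay over 0.1, and 8 of 9 arrays correlated best with their own number, a hint from the data and not from the design. A pairing in every comparison therefore stays possible. With a replicate block, 12 clusters were higher and 47 lower in C5aR+ than in C5aR- LysoDC, and 490 were higher and 219 lower in C5aR- LysoDC than in LysoMac. Higher in C5aR+ LysoDC than in both others were 0. The block moved no other count by over 1.5 times. In C5aR+ LysoDC against LysoMac it kept 15 of 17 calls and changed the call of no named gene or list other than Ccl8 and the macrophage list. No detection calls or background signals were used, so a lower limit of detection is not given.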

Other observations

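The tests of the signal range of LysoMac array 2, of other cell types in that array and of epithelial, M, conventional dendritic and B cells were chosen after the values were seen, as was the range of the variance ratio over left-out arrays. Beyond the groups described so far, 2 of 24 chemokine genes rose from LysoMac to C5aR- LysoDC, Ccl22 by 1.83 ± 0.33 and Ccl5 by 2.22 ± 0.41, while 5 rose and 1 fell adjusted over the list alone, but that list did not pass (adjusted p = 0.219). Of 24 chemokine and migration receptor genes 3 rose, among them Gpr183 (1.39 ± 0.27) and Ackr3 (1.10 ± 0.21), and 2 fell, among them Cx3cr1 (-0.98 ± 0.15), with 3 and 3 adjusted over the list alone, and that list did not pass either (adjusted p = 0.528). The antibody transport genes Pigr and Fcgrt rose by 3.23 ± 0.39 and 2.65 ± 0.44. The innate sensors Tlr7 and Tlr3 fell (-2.12 and -0.87, the latter a call lost with each array centred on its median), and so did Il1a (-1.61 ± 0.22) and the lipid genes Abca1 (-1.80 ± 0.24) and Fabp5 (-1.32 ± 0.20). Their lists did not pass in camera: 3 of 28 pattern recognition genes fell (adjusted p = 0.118), 1 of 22 inflammatory cytokines (adjusted p = 0.763) and 3 of 24 lipid genes (adjusted p = 0.111). Of the 29 lists, 11 passed in no comparison (adjusted p from 0.0824 to 0.911), among them type I interferon response, MHC class I presentation, glycolysis and the markers of T cells, neutrophils and plasmacytoid dendritic cells. Cd209a, chosen after its values were seen, has probes that disagree: one was -3.75 ± 0.47 in C5aR+ against C5aR- LysoDC and the other, brighter over all arrays, 0.53 ± 0.38. C5aR+ LysoDC array 3 stood apart within its group, at 1.01 above the mean of all arrays for Fc receptor genes (0.19 in arrays 1 and 2). It lay at 0.90 for monocyte genes (-0.066 and 0.025) and 0.61 for plasma cell genes (0.032 and -0.035). C5aR- LysoDC array 3 also lay highest in its group, at 0.51 for Fc receptor genes (0.047 and -0.076 in its arrays 1 and 2) and 0.54 for monocyte genes (0.17 and 0.14). LysoMac array 3 did not for monocyte genes (-0.65, against -0.53 and -0.52). C5aR+ LysoDC array 3 also lay highest for lists described above: 0.61 for macrophage genes (0.11 and 0.25 in arrays 1 and 2), 0.59 for B cell genes (0.069 and 0.14) and 0.79 for chemokines (0.33 and 0.41). For macrophage genes C5aR- LysoDC array 3 was highest in its group too (0.027, against -0.39 and -0.34). Without C5aR+ LysoDC array 3 the macrophage and chemokine lists against C5aR- LysoDC (adjusted p = 9.29e-07 and 0.00300) and the B cell and chemokine lists against LysoMac (adjusted p = 1.31e-10 and 8.36e-10) still passed at the preset correlation. With all arrays neither chemokine list passed with an estimated correlation (adjusted p = 0.264 and 0.119).

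LysoMac arrays varied more than the others, LysoMac array 2 most. Its slope on the mean of LysoMac arrays 1 and 3 over all clusters was 0.855, below the 0.967 to 1.09 of the other 8 arrays, so a compressed signal range may contribute. Quantile normalization brought that slope to 0.962, still the lowest. It moved the ratio of the variance in LysoMac to that in C5aR+ LysoDC only from 1.87 to 1.82 (1.65 to 2.58 with any 1 of the other 8 arrays left out). The bound of 1.5 set before the test also covered the ratio without array 2, which was 1.16 and did not meet it. Leaving out the array that stands apart removes every property of it, so the 1.16 does not say which property matters. With the bound not met, whether the range of array 2 is the whole cause stays open. The T cell list stood above 99.96% of 10000 random lists matched on expression in that array, with 9 of 15 genes highest there and Cd3d at 5.34 against 3.61 and 3.85, so a few T cells may be present, although the brightest genes of the list, Cd6 and Icos (6.08 and 6.60), did not stand above both other LysoMac arrays, 12 of the 15 lie above the median gene in LysoMac anyway, and the CD11c sort would remove T cells. No biological explanation was tested.

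Conventional dendritic cell genes were higher in C5aR- than in C5aR+ LysoDC. Epithelial cells in the C5aR- sort would raise the whole epithelial and M cell list (26 genes, 3 of them, Epcam, Ccl20 and Spib, in another list too). Its median rise was 0.020 (upper 95% bound 0.35 from a bootstrap over genes), against at least 2.11 for Gp2, Pglyrp1 and Cdh1. Those 3 are the members that passed, and 23 did not, so the median had to lie below them and the comparison cannot decide. In all, 14 members were higher in C5aR- LysoDC and 12 lower. Fabp1 (3.95) and Lgals4 (3.16), abundant in absorptive cells, stayed low, but 2 genes do not stand for the list. The list passed at the preset correlation (adjusted p = 0.0133) and not with an estimated correlation (adjusted p = 0.383). Epithelial cells as the source of the 3 rises stay open. M cells alone cannot be told apart from LysoDC that express these genes. A set of 8 genes that epithelial cells share had a median rise of 0.66 (95% bootstrap interval -0.0081 to 0.97). It holds Cdh1, 1 of the 3 rises to be explained. Epcam, Cldn7, Krt8 and Krt18 rose by 0.97, 0.85, 0.72 and 0.59, none of which passed, while Krt19, Cldn4 and Elf3 differed by 0.031, -0.0081 and -0.065. Spib, Sox8, Anxa5, Tnfaip2 and Ccl20, which the list holds beside Gp2, differed by 0.37, 0.35, 0.037, -0.0052 and -0.13. The CD11c sort would remove most M cells. Conventional dendritic cells, which the CD11c sort would not remove, cannot be told apart from a difference between the sorted populations themselves, which the design names and which stays open and untested, since no array of such cells was used here. If mixing with cells that lack a gene alone lowered it, the share of RNA from other cells would be at least 87.2% by Ccl8 and 50.2% by C5ar1, whose levels in C5aR- LysoDC lay below every array median and allow only a bound, 81.0% (95% interval 69.4 to 88.1) by Ms4a7, 41.0% (4.14 to 63.7) by C1qa, 38.6% (19.0 to 53.4) by C1qb, 48.8% (33.0 to 60.9) by C1qc, 45.4% (14.7 to 65.1) by Csf1r and 24.7% (-0.40 to 43.5) by Lyz2.

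MHC class II genes were higher in both LysoDC populations than in LysoMac, and B cells in the LysoDC sorts would raise B cell markers at least as much, since LysoMac express MHC class II themselves. The median rise of the 16 B cell genes was 0.75 in C5aR+ LysoDC (upper 95% bound 1.08 from a bootstrap over genes). In C5aR- LysoDC it was 0.60 with a bound of 1.15. Both lay below 1.66, the smallest rise of the 5 MHC class II genes that passed in both. Those 5 were picked by passing, and the smallest, H2-DMb1, lay below every array median in LysoMac, so that test cannot decide. The whole MHC class II list had medians of 0.84 and 1.66. H2-Aa, H2-Ab1 and H2-Eb1, fixed beforehand as sort targets, rose by 2.57, 2.34 and 2.48 in C5aR+ LysoDC. In C5aR- LysoDC they rose by 2.54, 2.39 and 2.50, also above both bounds, which argues against B cells as the source of their whole rise. Ighm, the brightest of the list, was not weighed, since its clusters disagree (-0.52 to 1.60 in C5aR+ LysoDC) and its level in LysoMac was high (10.5). A small share of B cells, which the rise of the markers themselves could reflect, is not excluded, although the CD11c sort would remove most B cells, 1 of the 16 genes is also in another list and 9 lie above the median gene in LysoMac. MHC class II was a target of the sort antibodies, so the gates may also set this difference, which remains open along with a difference between the populations.

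Other splits of the arrays were tested for each count. Of 100 splits of the 9 arrays into 3 groups of 3, 1 (the real one) gave as many as 255 clusters in the F test, with 47 as the highest other. For that count chance was excluded at 0.05. As many as 16 clusters higher or lower in both LysoDC populations came in 2 splits (highest other 27, in a split that left the C5aR- LysoDC arrays together). As many as the 1 cluster apart from both others came in 3 (highest other 10, in a split that left the LysoMac arrays together). Splits that mix populations that differ widen the spread and give few calls. They therefore test only that all 3 populations are alike, and do not exclude chance for these 2 counts. For that 1 cluster, Ccl8, 46 of the 100 splits part all same-numbered pairs of C5aR+ LysoDC and LysoMac, and 2 of them gave as many. Its count was 0 with a replicate block and without each of 7 arrays. Chance was not excluded for the 33 list calls with the preset correlation, which 13 of the 100 splits matched (highest other 44). As many as the 7 calls with an estimated correlation came in 1 split, the real one (highest other 3). Here too the splits test only that all 3 populations are alike, so chance is not excluded for a single list or comparison. The 6 arrays of a pairwise comparison make 10 splits, too few for a share under 0.05: the real split gave 34, 17 and 518 calls and the highest other 1, 0 and 0, so 1 of 10 splits matched in each. For C5aR+ LysoDC and LysoMac, 4 of the 10 splits part all 3 same-numbered pairs, and the 3 of them other than the real one gave 0 calls, as did those that keep a pair together.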
